A study of Mus musculus with 24 samples.

How the data were processed

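RNA-seq was analysed for 24 libraries of 3T9 mouse fibroblasts, in 8 groups of 3. The groups combine the vector the cells were infected with (empty vector, EV, or MycER in the WT, HEA or RA form) with the time in OHT (4 h or 8 h), as the labels give them. Per the labels' protocols, total RNA was purified on columns with DNase treatment and made into libraries with a stranded total RNA kit. The submitters' processing notes name TopHat2 2.0.8, TopHat, SAMtools, featureCounts 1.4.5-p1, DESeq2 and the mouse genome build mm9, with no role or order. The treatment of duplicate reads, the strand setting and the gene annotation are not given in the sources used here. The reference at hand was of another build, so no coordinates are printed, and it served only for gene names and transcript sequences.

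The authors deposited RPKM (reads scaled by gene length and library total) for 21671 genes in each library, per the file headers. The authors' deposited table of comparisons against EV holds baseMean (a mean of normalised counts), log2 fold changes with standard errors, p-values and adjusted p-values, per the file headers. Values from that table are printed only where it is named. Its fold changes and p-values went into no test here. Its baseMean values helped to set the gene lengths with which reads were recovered, so all uses of recovered reads below rest on them.

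RPKM values are not counts, so the test foreseen for count files did not apply. The form set beforehand for files of RPKM alone was used, limma-trend on log2(RPKM + 0.5). Genes with an RPKM of at least 1 in at least 3 libraries were tested, 12268 of 21671. All 24 libraries entered a single fit of the 8 group means with 16 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg within each comparison, with 0.05 as the threshold. A fold change on this scale understates the change of genes of low RPKM. Limma 3.58.1 was run in R 4.3.3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The groups, the comparisons, the test, the filter, the pseudocount, the gene lists, the rule for named genes and the alternatives given first below were chosen before the data were examined. The labels number the libraries of a group 1 to 3 without saying that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

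Low RPKM values step by the worth of a single read, which gave back whole reads: of 362673 values above 0, 99.9% lay within 0.01 read of a whole number, and 99.1% of the genes had whole reads in all libraries. The recovered totals ran from 9.82 to 12.8 M reads per library (median 10.9), the highest being 1.30 times the lowest. A gene at 0 reads could hold up to 3 reads, 0.235 to 0.306 CPM depending on the library, and this floor covers counting error only. Libraries of a group were compared pair by pair on these reads, and chi-square per degree of freedom was 1.46 to 18.8, above 1 in all pairs. The most abundant gene took 0.209 to 0.257% of a library's reads. Reads per base of gene, as the mean of 24 libraries, reached 1.91 among genes of 500 bases or more, and 244 genes were above 1 read per base. Gene copies that share reads, overlapping genes and antisense partners could not be told apart from these values.

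The genes named in the text follow a fixed rule. It takes Myc and Esr1, the 5 largest rises and 5 largest falls past the threshold in each comparison (mean of at least 1 RPKM, all 3 libraries of a group above all 3 of the other, predicted genes and multi-copy families passed over), the 3 members of each list with the smallest p in WT against EV at 8 h, up to 2 members going against a list's majority, and the Myc/Max network members that pass against EV. Genes named outside it are said to be chosen after their values were seen.

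There were 22 gene lists: general Myc targets, ribosome biogenesis, ribosomal proteins, translation factors and aminoacyl-tRNA synthetases, nucleotide and one-carbon metabolism, polyamines, glycolysis, mitochondrial biogenesis, cytosolic chaperones, G1/S and replication, mitosis, growth arrest, extracellular matrix, actin with SRF and YAP targets, immediate early genes, interferon and inflammation, p53 targets, ATF4 and amino acid supply, cholesterol synthesis, the circadian clock, lysosome and the Myc/Max network. A list of nuclear and RNA quality transcripts and 5 lists of other cell types (epithelial, macrophage, endothelial, muscle, adipocyte) were added. Of the 57 general Myc targets, 22 are also among the 64 ribosome biogenesis genes. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted within each comparison, and again with the correlation estimated from the residuals and with fry. The cell type lists were tested over all measured genes and adjusted over the 5 lists.

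The alternatives set beforehand were quantile normalisation, centring on library medians, no filter on low values, pseudocounts of 0.1 and 1, limma without the trend, the replicate number as a block, a fit of only the groups compared, and leaving out each library in turn. Chosen after seeing the data were limma-voom on the recovered reads, the score on the main axis of the spread within groups as a covariate, a fit without EV at 4 h replicate 2, WT at 4 h replicate 3 and WT at 8 h replicate 3, removal of a GC trend from each library, removal of a trend on reads per base of gene from each library, and CPM for the construct check. Removal of the trend on reads per base also takes away a real change shared by genes of similar reads per base. Shared EV libraries were allowed for with 100 simulated draws of unchanged groups. The test was checked on simulated reads with known changes. For the WT against EV comparison at 4 h, over 12100 genes, it called 30.6% of genes changed 1.25-fold, 66.0% at 1.5-fold, 88.0% at 2-fold and 98.0% at 4-fold. Of unchanged genes 0.0672% were called. The simulated reads were drawn gene by gene around the same level in all groups, with few genes changed and no spread shared between genes. These shares describe such reads and may not hold for the real libraries.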

Results

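The data cover 3T9 cells, an immortalised mouse fibroblast line, infected with an empty vector or with a MycER form and kept in OHT for 4 h or 8 h. MycER joins the transcription factor Myc to the hormone-binding domain of the oestrogen receptor, which OHT (4-hydroxytamoxifen) switches on. The 3 forms are WT, HEA and RA. HEA and RA are described as mutant Myc proteins, and the changed residues are not given in the sources used here. The series title asks how Myc's non-specific and sequence-specific contacts with DNA are required for gene regulation. Each of the 8 groups holds 3 libraries with a recovered depth of 9.82 to 12.8 M reads each. Group levels are mean RPKM ± SD of 3 libraries, fold changes are log2 ± SE on the scale of log2(RPKM + 0.5), and adjusted p-values are from limma over 12268 genes.

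Esr1, the oestrogen receptor gene whose hormone-binding part is in the constructs, served as a check of the labels. Its level was 0.277 ± 0.12 RPKM in EV at 4 h and 0.189 ± 0.097 at 8 h, against 11.9 ± 0.66 in WT, 11.5 ± 1.2 in HEA and 11.7 ± 0.62 in RA at 4 h. At 8 h it was 11.2 ± 2.3, 10.2 ± 0.88 and 11.2 ± 0.53 in the same order. Esr1 rose against EV by log2 fold changes of 3.96 ± 0.14 (HEA, 4 h) to 4.09 ± 0.14 (RA, 8 h), the lowest and highest of the 6 comparisons. The size depends on the scale: with CPM of recovered reads Esr1 was at 5.08 (HEA, 4 h) to 5.45 (RA, 8 h), with a pseudocount of 1 as low as 3.24 (HEA, 8 h) and with voom as high as 5.95 (RA, 8 h). Reads assigned to Myc went from 57.2 ± 4.7 RPKM in EV to 40.9 ± 10 in WT at 4 h and from 58.2 ± 1.9 to 38.8 ± 9.0 at 8 h. This fall had log2 fold changes of -0.51 ± 0.17 (adjusted p = 0.0286) and -0.60 ± 0.17 (adjusted p = 0.00754). In HEA the Myc values were -0.05 ± 0.17 and -0.24 ± 0.17 at 4 h and 8 h, and in RA 0.08 ± 0.17 and 0.12 ± 0.17, and none of these passed the test. Whether the construct's own Myc part adds reads to Myc is not given in the sources used here. The fall of Myc in WT at 4 h did not pass with median centring (adjusted p = 0.0524), with only the groups compared (0.128), without the 3 farthest libraries (0.303), or without EV at 4 h replicate 2 (0.0984), EV at 4 h replicate 3 (0.0572) or WT at 4 h replicate 3 (0.223). At 8 h it did not pass without WT at 8 h replicate 1 (0.0629).

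**Figure D1:**
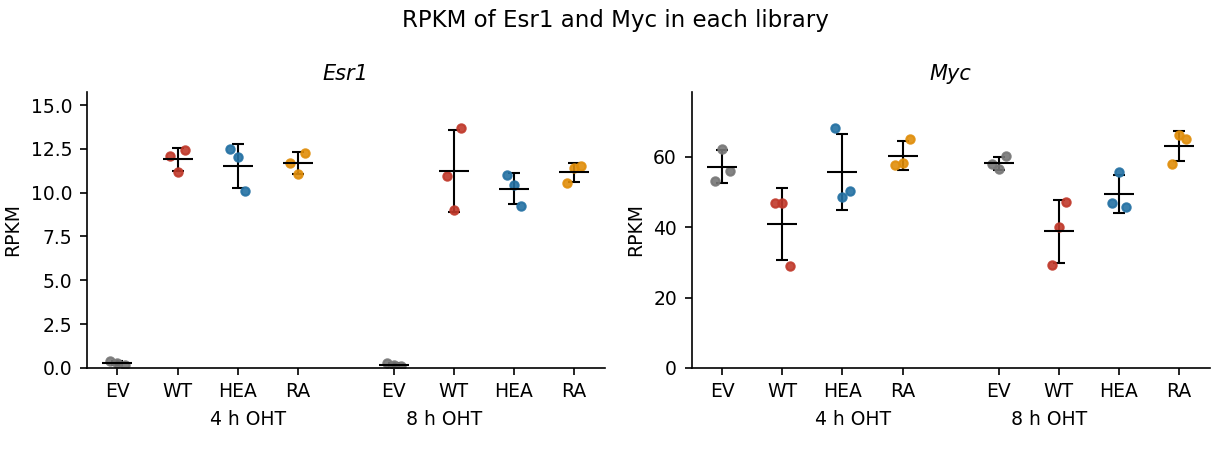
RPKM of Esr1 and Myc in each of the 24 libraries (points) by group, with the mean and SD of 3 libraries. Esr1 was below 0.5 RPKM in the EV groups' means and above 10.0 in all groups with MycER.

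WT was compared with EV at each time. Libraries without OHT were not used here, so the comparison does not separate what active MycER changed from differences the infected populations had before. At 8 h P2ry2, a receptor for extracellular nucleotides, went from 0.875 ± 0.23 to 11.1 ± 0.72 RPKM, a rise of 3.09 ± 0.14 (adjusted p = 6.85e-12). Reep6, Dgat2 and Ankrd6 rose by log2 fold changes of 2.59 ± 0.24, 2.51 ± 0.13 and 2.40 ± 0.18, with adjusted p at most 1.05e-07, Dgat2 being an enzyme of triglyceride synthesis. Asb5, Foxs1 and Fam214b fell, with log2 fold changes of -2.26 ± 0.24, -2.12 ± 0.16 and -2.05 ± 0.20 (adjusted p at most 4.52e-07). Ccng2, a cyclin linked to growth arrest, went from 33.0 ± 2.3 to 7.61 ± 1.1 RPKM (-2.05 ± 0.16), and Angptl4, a secreted inhibitor of lipoprotein lipase, from 13.9 ± 1.7 to 3.16 ± 0.83 (-2.00 ± 0.19). With voom the log2 fold changes were larger, 3.68 for P2ry2 and 3.18 for Ankrd6. In total 1861 genes were higher and 2463 lower in WT, 226 of them at least 2-fold higher and 265 at least 2-fold lower. The higher share of calls was 43.0%, and 55.2% with each library centred on its median.

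Genes for making ribosomes rose together in WT at 8 h. Of 63 tested genes of ribosome biogenesis, 50 rose, 0 fell and 13 did not pass, and adjusted over the list alone 52 were higher and 0 lower (camera adjusted p = 2.97e-20, adjusted p = 0.0616 with an estimated correlation). Rrp1b, Polr1b and Rrp9 rose by log2 fold changes of 0.77 ± 0.060, 0.82 ± 0.067 and 0.77 ± 0.072, where Polr1b is a subunit of RNA polymerase I and Rrp9 a part of the U3 snoRNP. Rrp9 went from 60.5 ± 3.3 to 104 ± 6.2 RPKM. Of 57 general Myc targets, 39 rose and 0 fell, or 40 and 0 adjusted over the list alone (adjusted p = 1.44e-14, adjusted p = 0.0616 with an estimated correlation). Dusp2, a phosphatase of MAP kinases, led them with 2.03 ± 0.15. In nucleotide and one-carbon metabolism 17 of 30 genes rose and 0 fell, or 17 and 1 adjusted over the list alone (adjusted p = 6.93e-06, adjusted p = 0.272 with an estimated correlation). Slc19a1, Mthfd1l and Pfas rose by log2 fold changes of 0.85 ± 0.080, 0.49 ± 0.066 and 0.37 ± 0.052. In that order they carry folate into the cell, take part in mitochondrial one-carbon metabolism and make purines.

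In mitochondrial biogenesis 17 of 36 genes rose and 0 fell, or 18 and 0 adjusted over the list alone (adjusted p = 1.28e-06, adjusted p = 0.218 with an estimated correlation). Timm9, Phb2 and Mrps30 rose by log2 fold changes of 0.56 ± 0.087, 0.36 ± 0.056 and 0.49 ± 0.089. Among ribosomal proteins 4 of 47 genes rose and 0 fell, or 1 and 0 adjusted over the list alone (adjusted p = 6.31e-05, adjusted p = 0.444 with an estimated correlation). Of these genes 30 were above 1 read per base, where reads follow the library total little and RPKM moves against it. With the trend on reads per base removed the list passed (adjusted p = 0.00866). Rps19 (0.28 ± 0.065), Rps13 (0.16 ± 0.049) and Rps18 (0.14 ± 0.047) passed. Recovered reads of Rps18 averaged 850 in EV and 871 in WT and those of Rps13 674 and 700, beside mean library totals of 11.7 and 10.8 M, so for these 2 genes a rise is not separated from the lower totals in WT. Rps19 averaged 825 and 930 reads at 0.558 reads per base. Rps13 did not pass without EV at 8 h replicate 3 (0.0585) or WT at 8 h replicate 3 (0.0629) with voom (0.0551) or without the 3 farthest libraries (0.0554). Rps18 did not pass without EV at 8 h replicate 1 (0.0624), EV at 8 h replicate 2 (0.0524), EV at 8 h replicate 3 (0.0576), WT at 8 h replicate 1 (0.0562) or WT at 8 h replicate 3 (0.08), with quantile normalisation (0.0852), without the trend (0.0565) or with voom (0.0762). Among translation factors and tRNA synthetases 12 of 39 genes rose and 1 fell, or 12 and 1 adjusted over the list alone (adjusted p = 0.0044, adjusted p = 0.444 with an estimated correlation). Farsa, Eef1d and Eif2b3 rose by log2 fold changes of 0.44 ± 0.055, 0.42 ± 0.065 and 0.45 ± 0.076. Cars, the cysteinyl-tRNA synthetase, went the other way (-0.25 ± 0.088), a call lost with median centring (0.154), with the trend on reads per base removed (0.0791) and without EV at 8 h replicate 1 (0.075), EV at 8 h replicate 2 (0.0728), EV at 8 h replicate 3 (0.058), WT at 8 h replicate 1 (0.13) or WT at 8 h replicate 2 (0.0908). Among cytosolic chaperones 8 of 25 genes rose and 1 fell, or 8 and 1 adjusted over the list alone (adjusted p = 0.0097, adjusted p = 0.444 with an estimated correlation). Dnajc2 and Fkbp4 rose by log2 fold changes of 0.44 ± 0.081 and 0.28 ± 0.059. Dnajb1 fell, with a log2 fold change of -0.41 ± 0.082. Mean reads per base were 1.09 for Rps18, 0.894 for Rps13, 0.946 for Fkbp4 and 0.840 for Phb2.

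In glycolysis 8 of 21 genes rose and 1 fell, or 9 and 1 adjusted over the list alone (adjusted p = 0.0353, adjusted p = 0.444 with an estimated correlation), and the call was lost without the 3 farthest libraries (adjusted p = 0.116) and with the trend on reads per base removed (0.071). Slc16a1 and Pfkfb3 rose by log2 fold changes of 0.47 ± 0.063 and 1.16 ± 0.18, a lactate carrier and a glycolytic regulator, and Eno2 fell, with a log2 fold change of -0.74 ± 0.13. Polyamine genes had 3 higher and 3 lower of 12, or 3 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.59, adjusted p = 0.791 with an estimated correlation). Its median log2 fold change was 0.03, its mean -0.04, and camera's direction was up. Srm and Odc1 rose by log2 fold changes of 0.33 ± 0.075 and 0.23 ± 0.054, enzymes making spermidine and putrescine, and Oaz2 fell, with a log2 fold change of -0.45 ± 0.11. Among genes of G1/S and replication 8 of 40 genes rose and 2 fell, or 8 and 2 adjusted over the list alone (adjusted p = 0.0263, adjusted p = 0.465 with an estimated correlation), and fry did not call it (0.0524). Cdc25a, Cdk6 and E2f2 rose by log2 fold changes of 0.33 ± 0.057, 0.47 ± 0.086 and 0.65 ± 0.17. Cdk2 fell, with a log2 fold change of -0.26 ± 0.067. Gins2 (-0.34 ± 0.10) passed but not without EV at 8 h replicate 1 (0.0525), EV at 8 h replicate 3 (0.0768) or WT at 8 h replicate 2 (0.0509). In mitosis 1 of 35 genes rose and 10 fell, or 1 and 10 adjusted over the list alone (adjusted p = 0.0138, adjusted p = 0.465 with an estimated correlation). Ccnb2, Cdc25c and Nusap1 fell, with log2 fold changes of -0.69 ± 0.099, -0.60 ± 0.10 and -0.89 ± 0.16, while Cdk1 rose by 0.17 ± 0.042.

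Growth arrest genes were lower in WT at 8 h. In the growth arrest list 2 of 30 genes rose and 16 fell, or 2 and 17 adjusted over the list alone (adjusted p = 0.000396, adjusted p = 0.123 with an estimated correlation). Besides Ccng2, Gadd45a and Ndrg4 fell, with log2 fold changes of -1.09 ± 0.087 and -1.05 ± 0.12, and Klf9 and Cebpa rose by log2 fold changes of 0.59 ± 0.12 and 0.62 ± 0.18 against the majority. Among immediate early genes 0 of 24 genes rose and 12 fell, or 0 and 13 adjusted over the list alone (adjusted p = 0.000384, adjusted p = 0.444 with an estimated correlation). Btg2, Ier3 and Dusp1 fell, with log2 fold changes of -1.38 ± 0.19, -0.74 ± 0.11 and -0.87 ± 0.14, where Btg2 is an antiproliferative factor and Dusp1 a phosphatase of MAP kinases. In the interferon and inflammation list 0 of 23 genes rose and 9 fell, or 1 and 10 adjusted over the list alone (adjusted p = 0.00415, adjusted p = 0.123 with an estimated correlation). Ddx58, Irf1 and Tnfaip3 fell, with log2 fold changes of -1.12 ± 0.11, -0.67 ± 0.070 and -1.11 ± 0.14, with Ddx58, a sensor of viral RNA, going from 5.73 ± 0.39 to 2.37 ± 0.26 RPKM. In the extracellular matrix list 0 of 35 genes rose and 10 fell, or 0 and 10 adjusted over the list alone (adjusted p = 0.0104, adjusted p = 0.49 with an estimated correlation). Loxl2, Col8a1 and Mfap5 fell, with log2 fold changes of -0.93 ± 0.12, -0.61 ± 0.10 and -1.39 ± 0.24, with -2.75 for Mfap5 with voom. Among actin, SRF and YAP target genes 0 of 30 genes rose and 9 fell, or 0 and 9 adjusted over the list alone (adjusted p = 0.0073, adjusted p = 0.46 with an estimated correlation). Actg2, Ankrd1 and Tgfb1i1 fell, with log2 fold changes of -1.35 ± 0.18, -1.49 ± 0.22 and -1.26 ± 0.21.

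In cholesterol synthesis 2 of 23 genes rose and 11 fell, or 2 and 11 adjusted over the list alone (adjusted p = 0.0138, adjusted p = 0.444 with an estimated correlation). Hsd17b7, Mvd and Tm7sf2 fell, with log2 fold changes of -1.07 ± 0.10, -0.88 ± 0.15 and -0.57 ± 0.13. Dhcr7, the last enzyme of the pathway, rose by 0.42 ± 0.11, and Lss (0.28 ± 0.11) passed but not without EV at 8 h replicate 2 (0.0953), EV at 8 h replicate 3 (0.163), WT at 8 h replicate 1 (0.13) or WT at 8 h replicate 3 (0.108), without the filter (0.063), without the trend (0.0531), with the axis covariate (0.0558) or without the 3 farthest libraries (0.103). Among lysosomal genes 1 of 33 genes rose and 10 fell, or 1 and 10 adjusted over the list alone (adjusted p = 0.0297, adjusted p = 0.444 with an estimated correlation), and the call was lost with median centring (0.0726). Sqstm1 and Atp6v0d1 fell, with log2 fold changes of -0.41 ± 0.065 and -0.52 ± 0.084, and Gusb rose by a log2 fold change of 0.64 ± 0.088. The lists of p53 targets (5 higher and 9 lower of 25, 5 and 9 adjusted over the list alone, adjusted p = 0.248) and of ATF4 and amino acid supply (4 and 12 of 30, 4 and 13 adjusted over the list alone, adjusted p = 0.114) did not pass, with adjusted p = 0.444 and 0.523 with an estimated correlation. Nupr1 and Chac1 fell, with log2 fold changes of -0.70 ± 0.058 and -1.05 ± 0.095. Chac1 takes part in breaking down glutathione. In turn the amino acid carriers Slc1a5 and Slc7a1 rose by log2 fold changes of 0.63 ± 0.083 and 0.52 ± 0.13. Of p53 targets, Tnfrsf10b fell, with a log2 fold change of -0.47 ± 0.072, and Aen rose by a log2 fold change of 0.40 ± 0.074. None of the 17 lists called held with an estimated correlation.

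**Figure D2:**
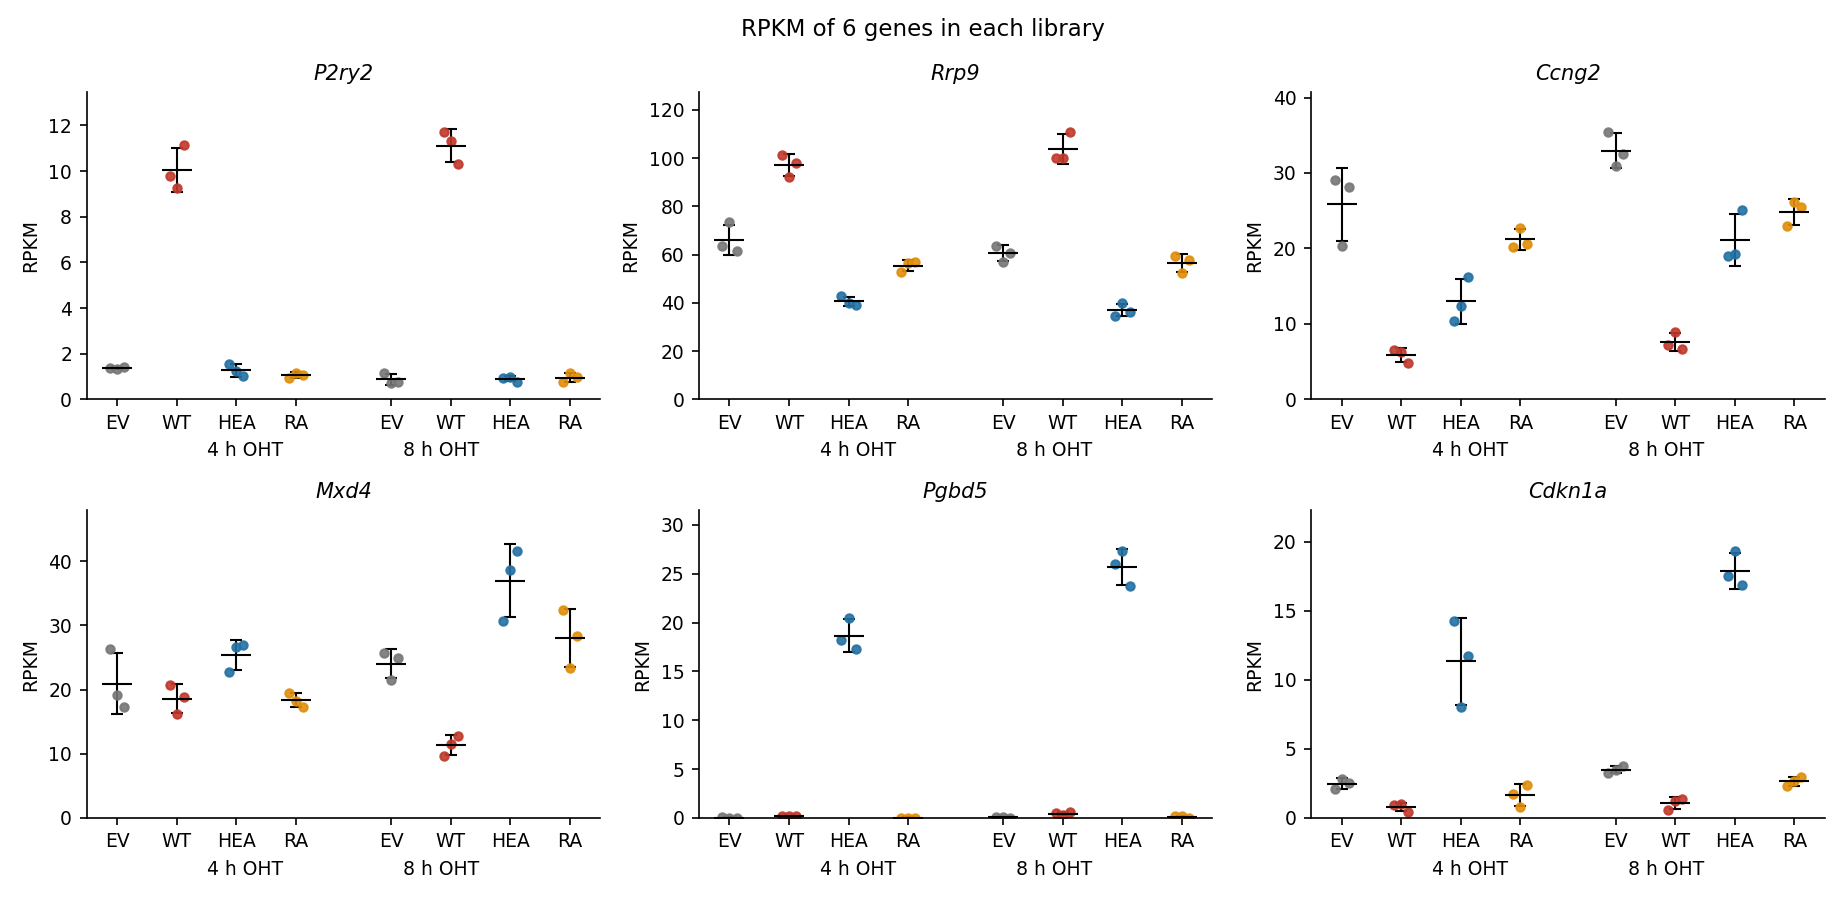
RPKM of P2ry2, Rrp9, Ccng2, Mxd4, Pgbd5 and Cdkn1a in each library (points) by group, with the mean and SD of 3 libraries. P2ry2 and Rrp9 are highest in WT, and Pgbd5 and Cdkn1a in HEA.

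At 4 h of OHT 1429 genes were higher and 1767 lower in WT than in EV, 96 of them at least 2-fold higher and 106 at least 2-fold lower. Rgcc, a regulator of the cell cycle, went from 1.72 ± 0.39 to 16.5 ± 5.8 RPKM (2.90 ± 0.27), and P2ry2 from 1.37 ± 0.035 to 10.1 ± 0.96 (2.49 ± 0.14), both rises. Rasl11a and Ica1 rose by log2 fold changes of 2.20 ± 0.24 and 2.11 ± 0.13. Ccng2, Adamts7, Adamts4, Fam214b and Nynrin fell, with log2 fold changes of -2.04 ± 0.16, -1.94 ± 0.20, -1.86 ± 0.21, -1.85 ± 0.20 and -1.56 ± 0.26, with adjusted p at most 0.000159. Adamts4 and Adamts7 are secreted proteases of the matrix. In ribosome biogenesis 43 of 63 genes rose and 0 fell, or 49 and 0 adjusted over the list alone (adjusted p = 1.6e-17, adjusted p = 0.0994 with an estimated correlation), with Polr1b at 0.74 ± 0.067. Among growth arrest genes 3 of 30 genes rose and 14 fell, or 3 and 15 adjusted over the list alone (adjusted p = 0.00387, adjusted p = 0.187 with an estimated correlation). In mitosis 0 of 35 genes rose and 15 fell, or 1 and 16 adjusted over the list alone (adjusted p = 0.00275, adjusted p = 0.59 with an estimated correlation). The higher share of calls was 44.7%, and 57.3% with median centring. The count of 3196 was 2040 without WT at 4 h replicate 3 and 1112 with only the groups compared.

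Of the other lists in WT at 4 h, general Myc targets (34 higher and 1 lower, adjusted p = 4.34e-13), nucleotide and one-carbon genes (18 and 0, 9.06e-08) and mitochondrial biogenesis (15 and 0, 3.34e-07) were up. Adjusted over the list alone they had 40 and 1, 20 and 1, and 17 and 0, higher and lower. With an estimated correlation their adjusted p = 0.0994, 0.187 and 0.187. Ribosomal proteins had higher RPKM (11 and 0, or 10 and 0 adjusted over the list alone, adjusted p = 2.74e-06, adjusted p = 0.59 with an estimated correlation), a call lost with the trend on reads per base removed (0.125). Recovered reads averaged 861 in EV and 861 in WT for Rps18 and 700 and 684 for Rps13, beside mean library totals of 11.1 and 10.1 M, so a rise of ribosomal protein transcripts at 4 h is not shown. Immediate early genes (0 and 6, adjusted p = 0.0136, adjusted p = 0.59 with an estimated correlation) were down, or 0 and 7 adjusted over the list alone, and the call was lost without the 3 farthest libraries (0.104). Among translation factors and tRNA synthetases 12 of 39 genes rose and 2 fell, or 12 and 2 adjusted over the list alone (adjusted p = 0.00216, adjusted p = 0.59 with an estimated correlation), a call lost with the trend on reads per base removed (0.148). Among cytosolic chaperones 9 of 25 genes rose and 3 fell, or 13 and 3 adjusted over the list alone (adjusted p = 0.0413, adjusted p = 0.59 with an estimated correlation), a call lost with median centring (0.0768), with fry (0.0908) and with the trend on reads per base removed (0.377). In the extracellular matrix list 0 of 35 genes rose and 8 fell, or 0 and 8 adjusted over the list alone (adjusted p = 0.025, adjusted p = 0.635 with an estimated correlation), a call lost with median centring (0.0506), with fry (0.0824) and without the 3 farthest libraries (0.561). Slc19a1 and Timm9 rose by 0.45 ± 0.080 and 0.56 ± 0.087, and Btg2 and Dusp1 fell, with log2 fold changes of -0.92 ± 0.19 and -0.67 ± 0.14. Of the genes higher in WT at 4 h, 1039 were also higher at 8 h (216.8 for independent lists), and 1220 were lower at both (354.8). No gene passed in opposite directions, a count of 0 from limma. The EV libraries differ between the times.

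HEA was compared with EV in the same way. At 8 h Pgbd5, a gene derived from a piggyBac transposase, went from 0.0503 ± 0.016 to 25.7 ± 1.9 RPKM, a rise of 5.57 ± 0.14 (adjusted p = 1.66e-16). Hpse, Fzd9 and Engase rose by log2 fold changes of 3.69 ± 0.18, 3.69 ± 0.18 and 3.31 ± 0.15 (adjusted p at most 7.51e-12), coding for heparanase, a Wnt receptor and a glycan-cleaving enzyme. Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, went from 3.48 ± 0.23 to 17.9 ± 1.3 RPKM (2.21 ± 0.26, adjusted p = 9.21e-07). Fgf2, Ccbe1, Chil1, Eva1a and Agtrap fell, with log2 fold changes of -2.50 ± 0.24, -2.34 ± 0.27, -2.17 ± 0.27, -2.13 ± 0.15 and -2.07 ± 0.17 (adjusted p at most 1.67e-06). Fgf2 is a growth factor of fibroblasts. Frat1, Trim7 and Inhbb rose by log2 fold changes of 2.94 ± 0.20, 2.79 ± 0.15 and 2.57 ± 0.23. With voom the changes were larger, 8.64 for Pgbd5, 4.73 for Hpse, 4.55 for Frat1, 4.03 for Inhbb, -3.33 for Fgf2 and -3.55 for Chil1, while a pseudocount of 1 gave 4.67 for Pgbd5 and 2.31 for Frat1. In total 2474 genes were higher and 3379 lower, 466 of them at least 2-fold higher and 330 at least 2-fold lower. The higher share was 42.3%, and 53.6% with median centring.

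Ribosome biogenesis genes were lower in HEA at 8 h, with 5 of 63 higher and 43 lower, or 5 and 44 adjusted over the list alone (adjusted p = 4.69e-07, adjusted p = 0.929 with an estimated correlation). Rrp9, Polr1b and Rrp1b fell, with log2 fold changes of -0.70 ± 0.072, -0.60 ± 0.067 and -0.41 ± 0.060. Rrp9 went from 60.5 ± 3.3 to 37.0 ± 2.6 RPKM. Among general Myc targets 4 of 57 genes rose and 31 fell, or 4 and 32 adjusted over the list alone (adjusted p = 0.000701, adjusted p = 0.929 with an estimated correlation). In nucleotide and one-carbon metabolism 5 of 30 genes rose and 16 fell, or 6 and 17 adjusted over the list alone (adjusted p = 0.0269, adjusted p = 0.929 with an estimated correlation), with Pfas at -0.51 ± 0.052 and Slc19a1 at -0.50 ± 0.080. In G1/S and replication 3 of 40 genes rose and 19 fell, or 3 and 19 adjusted over the list alone (adjusted p = 0.0269, adjusted p = 0.929 with an estimated correlation). Cdk2 and E2f2 fell, with log2 fold changes of -0.65 ± 0.067 and -0.70 ± 0.17. In mitosis 0 of 35 genes rose and 22 fell, or 0 and 23 adjusted over the list alone (adjusted p = 0.00208, adjusted p = 0.929 with an estimated correlation). Ccnb2, Cdc25c and Nusap1 fell, with log2 fold changes of -0.38 ± 0.099, -0.51 ± 0.10 and -0.65 ± 0.16. With median centring the nucleotide list (0.0735) and the G1/S list (0.0777) did not pass, and with the trend on reads per base removed they had 0.067 and 0.0731. Among single members of lists that did not pass, Actg2, Tgfb1i1 and Slc1a5 fell, with log2 fold changes of -1.55 ± 0.18, -1.35 ± 0.21 and -0.81 ± 0.083, and Irf1, Vldlr and Atp6v0d1 rose by log2 fold changes of 0.49 ± 0.070, 0.69 ± 0.13 and 0.45 ± 0.084.

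At 4 h HEA differed from EV in 2176 higher and 3127 lower genes, of which 402 were at least 2-fold higher and 225 at least 2-fold lower. Pgbd5, Fzd9, Hpse and Peli3 rose by log2 fold changes of 5.18 ± 0.14, 3.77 ± 0.18, 3.43 ± 0.18 and 3.00 ± 0.20 (adjusted p at most 4.71e-10). Chil1, Egr2, Cdc42ep5, Gsta4 and Nyap1 fell, with log2 fold changes of -2.29 ± 0.27, -1.94 ± 0.24, -1.92 ± 0.30, -1.72 ± 0.31 and -1.71 ± 0.16 (adjusted p at most 0.000188), Egr2 being a zinc finger factor of the immediate early class and Gsta4 a glutathione transferase. With voom the values were 9.23 for Pgbd5, 4.42 for Hpse, 4.79 for Peli3 and -3.22 for Chil1. Cdkn1a rose by 1.96 ± 0.26, from 2.49 ± 0.37 to 11.3 ± 3.1 RPKM. In ribosome biogenesis 2 of 63 genes rose and 47 fell, or 3 and 48 adjusted over the list alone (adjusted p = 8.63e-09, adjusted p = 0.781 with an estimated correlation), and Polr1b was at -0.52 ± 0.067. Among general Myc targets 3 of 57 genes rose and 36 fell, or 4 and 36 adjusted over the list alone (adjusted p = 4.63e-05, adjusted p = 0.781 with an estimated correlation). In G1/S and replication 3 of 40 genes rose and 25 fell, or 3 and 26 adjusted over the list alone (adjusted p = 0.000352, adjusted p = 0.781 with an estimated correlation), with Cdk2 at -0.86 ± 0.067. The lists of mitosis (0 higher and 19 lower, adjusted p = 0.00461), cholesterol synthesis (1 and 15, 0.00882) and nucleotide and one-carbon metabolism (3 and 17, 0.00461) were down, each with adjusted p = 0.781 with an estimated correlation. Adjusted over the list alone they had 0 and 19, 1 and 15, and 3 and 20, higher and lower. The mitosis call was lost with the trend on reads per base removed (0.0822). Of the genes higher at 4 h, 1899 were also higher at 8 h (438.8 for independent lists), and 2668 were lower at both (861.3). In opposite directions 2 genes were higher at 4 h and lower at 8 h, and 1 was lower at 4 h and higher at 8 h.

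RA against EV gave far fewer calls, 317 genes higher and 335 lower at 4 h, of which 13 and 13 changed at least 2-fold. Ccl7, a chemokine, went from 10.8 ± 2.5 to 29.2 ± 5.0 RPKM (1.41 ± 0.17, adjusted p = 0.000237) and Veph1 rose by 1.08 ± 0.20. Ctxn1, Fgf2, Dyrk3, Nat8l and Adamts7 fell, with log2 fold changes of -1.53 ± 0.18, -1.43 ± 0.24, -1.33 ± 0.20, -1.27 ± 0.24 and -1.27 ± 0.20 (adjusted p at most 0.00519), where Dyrk3 is a kinase and Nat8l makes N-acetylaspartate. Dhrs3 (1.45 ± 0.33), a retinaldehyde reductase, passed but not without EV at 4 h replicate 2 (0.103), RA at 4 h replicate 1 (0.0959) or RA at 4 h replicate 2 (0.0511), nor without the 3 farthest libraries (0.085). U90926 (1.37 ± 0.38) did not pass without EV at 4 h replicate 2 (0.258), RA at 4 h replicate 1 (0.104), RA at 4 h replicate 2 (0.168) or RA at 4 h replicate 3 (0.0509), without the 3 farthest libraries (0.217) or without the filter (0.0661). In ribosome biogenesis 0 of 63 genes rose and 11 fell, or 0 and 34 adjusted over the list alone (adjusted p = 4.87e-17, adjusted p = 0.109 with an estimated correlation). Rrp1b fell, with a log2 fold change of -0.32 ± 0.060. Among general Myc targets 0 of 57 genes rose and 9 fell, or 0 and 15 adjusted over the list alone (adjusted p = 3.77e-09, adjusted p = 0.152 with an estimated correlation). In the interferon and inflammation list 6 of 23 genes rose and 0 fell, or 8 and 0 adjusted over the list alone (adjusted p = 0.000179, adjusted p = 0.0865 with an estimated correlation). Ddx58 rose by a log2 fold change of 0.74 ± 0.11, against -0.79 ± 0.11 in WT.

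The count of 652 for RA at 4 h was 158 without EV at 4 h replicate 2, 381 without EV at 4 h replicate 3, 205 without RA at 4 h replicate 1 and 228 without RA at 4 h replicate 2. It was 335 without the 3 farthest libraries, 980 with the GC trend removed and 1550 with the axis covariate. With only the groups compared it was 3, and of the genes named for RA at 4 h only Esr1 then passed, the others lying between adjusted p = 0.0541 (Dyrk3) and 0.127 (Dhrs3). The other lists called at 4 h rest on 0 to 3 passing members each, all lower in RA: glycolysis (3 lower of 21, camera adjusted p = 0.0135), nucleotide and one-carbon metabolism (2 lower of 30, camera adjusted p = 0.00425), chaperones (2 lower of 25, camera adjusted p = 0.0218), ATF4 and amino acid supply (2 lower of 30, camera adjusted p = 0.0135), G1/S and replication (1 lower of 40, camera adjusted p = 0.0244), cholesterol synthesis (1 lower of 23, camera adjusted p = 0.0244), mitosis (0 lower of 35, camera adjusted p = 0.0135), translation factors (0 lower of 39, camera adjusted p = 0.0154) and ribosomal proteins (0 lower of 47, camera adjusted p = 0.0344). In each of these lists 0 genes were higher, and adjusted over the list alone they had 3, 3, 3, 2, 1, 2, 0, 0 and 0 genes lower in the same order. With an estimated correlation they ran from adjusted p = 0.532 to 0.8. With fry none of the 9 passed (0.105 to 0.632), nor with the trend on reads per base removed (0.0762 to 0.922). Without the 3 farthest libraries translation factors (0.171), glycolysis (0.117), chaperones (0.171) and G1/S (0.117) did not pass, and the ribosomal protein list turned upward (adjusted p = 0.941).

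At 8 h 183 genes were higher and 158 lower in RA, 21 and 7 of them at least 2-fold. Cemip, which takes part in breaking down hyaluronan, went from 12.54 ± 1.2 to 31.0 ± 3.9 RPKM (1.27 ± 0.23, adjusted p = 0.00527), and Lctl rose by 1.35 ± 0.18. Dyrk3, Ctxn1 and Arhgdig fell, with log2 fold changes of -1.31 ± 0.20, -1.16 ± 0.18 and -1.08 ± 0.12 (adjusted p at most 0.00219). Sned1 (1.33 ± 0.25) and Nat8l (-1.23 ± 0.24) passed but not without RA at 8 h replicate 1 (0.0656) for Sned1 and RA at 8 h replicate 1 (0.0586) for Nat8l. Sned1 was at 2.00 with voom. Ccbe1 (-1.34 ± 0.27) did not pass without EV at 8 h replicate 2 (0.0542) or RA at 8 h replicate 1 (0.0736). Complement gene C3 (1.29 ± 0.33) did not pass without EV at 8 h replicate 1 (0.167), EV at 8 h replicate 2 (0.0639), EV at 8 h replicate 3 (0.0994), RA at 8 h replicate 1 (0.227), RA at 8 h replicate 2 (0.0559) or RA at 8 h replicate 3 (0.074) or without the filter (0.0615). In ribosome biogenesis 0 of 63 genes rose and 3 fell, or 0 and 13 adjusted over the list alone (adjusted p = 8.96e-13, adjusted p = 0.207 with an estimated correlation), with no passing change of Polr1b (-0.23 ± 0.067). Among general Myc targets 0 of 57 genes rose and 2 fell, or 0 and 4 adjusted over the list alone (adjusted p = 1.55e-07, adjusted p = 0.207 with an estimated correlation). In the interferon and inflammation list 3 of 23 genes rose and 0 fell, or 4 and 0 adjusted over the list alone (adjusted p = 0.00157, adjusted p = 0.207 with an estimated correlation). Lists resting on 0 or 1 passing member were mitosis (0 higher and 1 lower of 35, adjusted p = 6.54e-05), nucleotide and one-carbon metabolism (0 higher and 1 lower of 30, adjusted p = 0.000428), cholesterol synthesis (0 higher and 1 lower of 23, adjusted p = 0.00263) and G1/S and replication (0 higher and 0 lower of 40, adjusted p = 0.0411) downward, and extracellular matrix (1 higher and 0 lower of 35, adjusted p = 0.0232) and actin targets (1 higher and 0 lower of 30, adjusted p = 0.0285) upward, with adjusted p = 0.388 to 0.65 with an estimated correlation. Adjusted over the list alone they had 0 and 1, 0 and 3, 0 and 2, 0 and 0, 1 and 0, 1 and 0, higher and lower. With fry the nucleotide (0.109), G1/S (0.386), mitosis (0.109), matrix (0.386), actin (0.337) and cholesterol (0.123) lists did not pass. With median centring the G1/S (0.065), matrix (0.0645) and actin (0.0645) lists did not, and with the trend on reads per base removed the G1/S list did not (0.266).

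The 341 genes called for RA at 8 h were 111, 142 and 89 without EV at 8 h replicates 1, 2 and 3, and 59, 157 and 189 without RA at 8 h replicates 1, 2 and 3. They were 1310 with only the groups compared, 526 with voom, 684 with the GC trend removed and 850 with the axis covariate. Of the genes higher in RA at 4 h, such as Ccl7 (1.41 ± 0.17 and 0.98 ± 0.17 at 4 h and 8 h), 94 were also higher at 8 h (4.73 for independent lists), and 107 were lower at both (4.31), Dyrk3 among them.

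**Figure D3:**
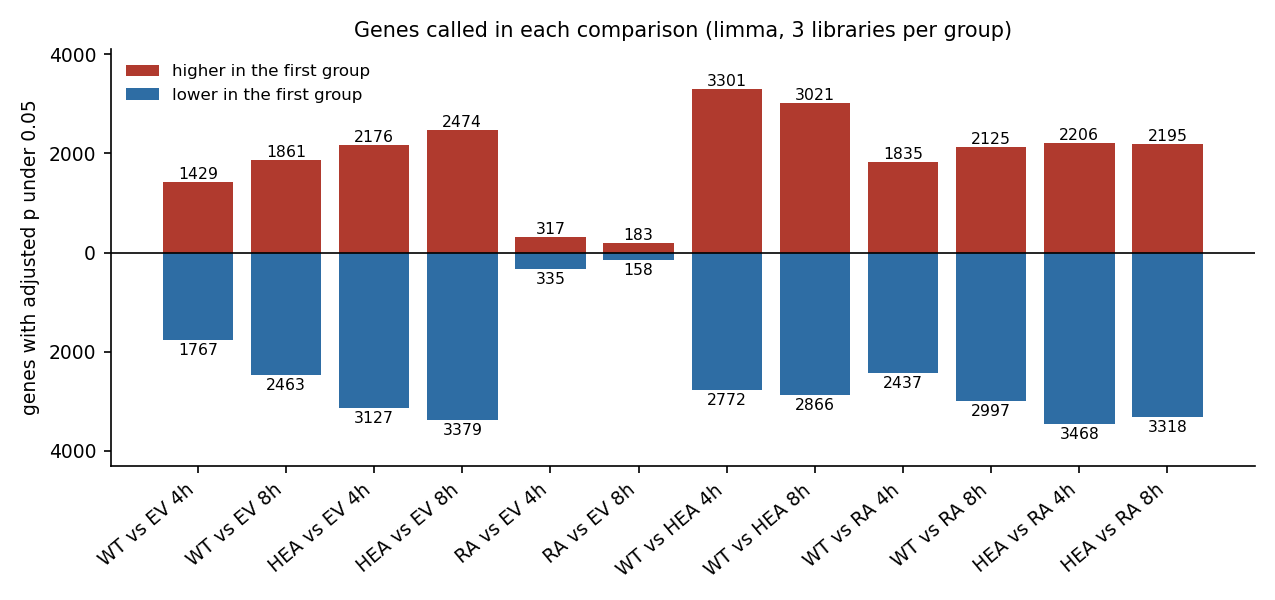
Number of genes called higher and lower (limma adjusted p under 0.05) among 12268 tested in each of 12 comparisons, 6 against EV and 6 between MycER forms. RA against EV has 652 calls at 4 h and 341 at 8 h, and HEA against EV 5303 and 5853.

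WT was set directly against HEA. At 8 h Smpdl3b, P2ry2, Dusp9, Pomgnt2 and St6galnac4 rose by log2 fold changes of 3.28 ± 0.11, 3.05 ± 0.14, 2.90 ± 0.24, 2.80 ± 0.12 and 2.73 ± 0.069, in WT over HEA (adjusted p at most 5.13e-09). St6galnac4, a sialyltransferase, stood at 49.1 ± 3.1 RPKM in WT, 6.98 ± 0.49 in HEA and 12.8 ± 0.50 in EV. Lower in WT than in HEA were Pgbd5, Cdkn1a, Hpse, Engase and Trim7 (-4.84 ± 0.14, -3.61 ± 0.26, -3.61 ± 0.18, -3.40 ± 0.15 and -3.22 ± 0.15). With voom the differences were -5.97 for Pgbd5, -4.54 for Hpse, -4.13 for Trim7 and 4.77 for Dusp9. Cdkn1a stood at 1.05 ± 0.43 RPKM in WT against 17.9 ± 1.3 in HEA, on either side of EV. The count was 3021 higher and 2866 lower, 443 and 592 of them at least 2-fold. In ribosome biogenesis 57 of 63 genes were higher in WT and 0 lower, or 58 and 0 adjusted over the list alone (adjusted p = 3.14e-23, adjusted p = 0.0399 with an estimated correlation). Among general Myc targets 47 of 57 genes were higher and 0 lower, or 48 and 2 adjusted over the list alone (adjusted p = 1.1e-15, adjusted p = 0.0399 with an estimated correlation). In the extracellular matrix list 0 of 35 genes were higher and 19 lower, or 0 and 19 adjusted over the list alone (adjusted p = 0.000282, adjusted p = 0.614 with an estimated correlation). Among growth arrest genes 1 of 30 genes were higher and 16 lower, or 1 and 17 adjusted over the list alone (adjusted p = 0.00102, adjusted p = 0.174 with an estimated correlation).

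At 4 h Chil1, P2ry2, Dusp9, Dusp2 and Pomgnt2 were higher in WT than in HEA (2.62 ± 0.27, 2.58 ± 0.14, 2.42 ± 0.24, 2.36 ± 0.15 and 2.35 ± 0.12) and Pgbd5, Hpse, Cdkn1a, Frat1 and Inhbb lower (-4.83 ± 0.14, -3.25 ± 0.18, -3.20 ± 0.26, -3.12 ± 0.20 and -3.07 ± 0.23), with adjusted p at most 1.15e-07. With voom the differences were -6.61 for Pgbd5, -4.04 for Hpse, -3.87 for Cdkn1a, -5.02 for Frat1, -4.80 for Inhbb, 4.20 for Dusp9 and 3.60 for Chil1. The count was 3301 higher and 2772 lower, and 3945 in all with only the groups compared, against 6073. In ribosome biogenesis 54 of 63 were higher in WT and 0 lower, or 54 and 0 adjusted over the list alone (adjusted p = 1.71e-21, adjusted p = 0.0501 with an estimated correlation). General Myc targets had 45 higher and 0 lower, or 46 and 0 adjusted over the list alone (adjusted p = 4.21e-15, adjusted p = 0.0501 with an estimated correlation).

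Set against RA, WT had Reep6, P2ry2, Kcng1, Dgat2 and Cited1 higher at 8 h (3.30 ± 0.24, 3.00 ± 0.14, 2.65 ± 0.34, 2.56 ± 0.13 and 2.55 ± 0.25) and Fam214b, Foxs1, Gprc5c, Ypel3 and Asb5 lower (-2.45 ± 0.20, -2.19 ± 0.16, -2.05 ± 0.34, -1.92 ± 0.25 and -1.91 ± 0.24), with adjusted p at most 7.51e-05. With voom Kcng1 was at 3.58. At 4 h Rgcc, P2ry2, Tmem158, Dyrk3 and Reep6 were higher (3.10 ± 0.27, 2.77 ± 0.14, 2.54 ± 0.17, 2.41 ± 0.20 and 2.29 ± 0.24) and Fam214b, Nynrin, Ccng2, Suox and Mpp2 lower (-2.02 ± 0.20, -1.81 ± 0.26, -1.78 ± 0.16, -1.74 ± 0.17 and -1.59 ± 0.17), with adjusted p at most 1.99e-05. The counts were 2125 higher and 2997 lower at 8 h, and 1835 higher and 2437 lower at 4 h. In ribosome biogenesis 61 of 63 genes were higher in WT at 8 h and 59 at 4 h, or 62 and 60 adjusted over the list alone, with 0 lower at either time (adjusted p = 8.78e-28 and 4.45e-30, and adjusted p = 0.0189 and 0.0136 with an estimated correlation). The interferon and inflammation list had 13 of 23 genes lower in WT than in RA at 8 h and 0 higher, or 0 and 14 (higher and lower) adjusted over the list alone (adjusted p = 7.94e-05, adjusted p = 0.0257 with an estimated correlation). At 4 h the higher share of calls was 43.0%, and 55.6% with median centring, and the 4272 calls were 2793 with only the groups compared.

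HEA and RA were compared last. At 8 h Pgbd5, Fzd9, Hpse, Engase and Frat1 were higher in HEA (5.39 ± 0.14, 3.62 ± 0.18, 3.50 ± 0.18, 3.00 ± 0.15 and 2.90 ± 0.20) and Chil1, C3, Islr, Eva1a and Cdo1 lower (-2.86 ± 0.27, -2.62 ± 0.33, -2.29 ± 0.45, -2.15 ± 0.15 and -1.99 ± 0.46), with adjusted p at most 0.00142. At 4 h Trim7 was among the largest rises (2.72 ± 0.15) and Slpi, a secreted protease inhibitor, among the largest falls (-2.38 ± 0.32). With voom the differences were 7.78 for Pgbd5, 4.36 for Hpse, 4.25 for Frat1, -4.33 for Chil1 and -3.37 for C3 at 8 h, and -3.55 for Slpi at 4 h. The counts were 2195 higher and 3318 lower at 8 h and 2206 higher and 3468 lower at 4 h. Of the 22 lists, 0 passed between HEA and RA at either time with camera at the preset correlation. The smallest adjusted p among them was 0.0862 at 8 h and 0.0919 at 4 h.

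**Figure D4:**
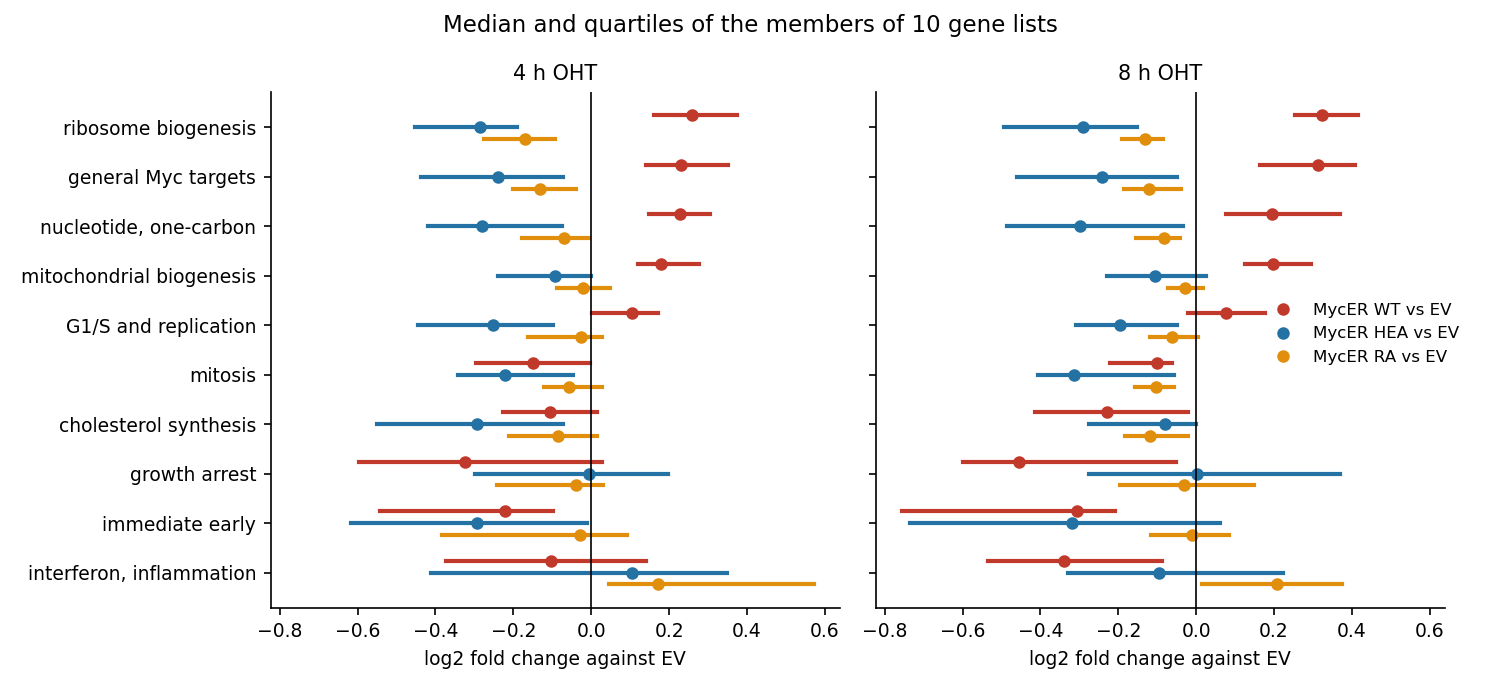
Median log2 fold change against EV (points) with quartiles over the tested members (bars) of 10 gene lists, for WT, HEA and RA at 4 h and 8 h. Ribosome biogenesis has a median of 0.32 in WT and -0.29 in HEA at 8 h.

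The forms were also compared through their changes against EV, which share the 3 EV libraries of a time. At 8 h 646 genes were higher and 1112 lower in both WT and HEA, against 375.3 and 678.4 for independent lists. Simulated unchanged groups shared 0 calls, but they hold almost no calls, so that value is no reference for lists this long. Of the genes called in both, Fzd9, a Wnt receptor, rose by 2.18 ± 0.18 in WT and 3.69 ± 0.18 in HEA, and Suox, a sulfite oxidase, was at -1.65 ± 0.17 and -1.70 ± 0.17. Opposite calls numbered 432 for genes higher in WT and lower in HEA (512.6 for independent lists) and 366 for the reverse (496.7); Rrp9 belonged to the former and Cdkn1a to the latter. WT and RA shared 23 higher and 56 lower genes at 8 h (27.8 and 31.7), HEA and RA 103 and 91 (36.9 and 43.5). Opposite calls of WT and RA at 8 h were 51 genes higher in WT and lower in RA (23.97) and 38 for the reverse (36.7). For HEA and RA they were 24 higher in HEA and lower in RA (31.9) and 20 for the reverse (50.4). At 4 h the shared counts were 425 and 735 for WT and HEA (253.5 and 450.4), 35 and 94 for WT and RA (36.9 and 48.3), and 114 and 186 for HEA and RA (56.2 and 85.4). Opposite calls at 4 h were 339 and 252 for WT and HEA (364.2 and 313.4), 95 and 24 for WT and RA (39.02 and 45.7), and 46 and 43 for HEA and RA (59.4 and 80.8), genes higher in the form named first being given first. The 3 EV libraries of a time were not split between the forms, so part of any excess can come from the shared controls.

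Across genes, which are not independent replicates, the log2 fold changes of WT and HEA had a Pearson r of 0.246 at 4 h and 0.308 at 8 h (Spearman 0.188 and 0.281). Those of WT and RA had 0.157 and 0.147 (0.120 and 0.0805), and HEA and RA 0.226 and 0.354 (0.181 and 0.321). Simulated unchanged groups with a shared control, drawn from the residuals of all 24 libraries, gave 0.465 on average (SD 0.22, highest 0.819, Spearman 0.426) over 100 draws. These groups hold no changes of their own, so their r is no reference for comparisons that hold real changes. The covariances were 0.0457 and 0.0743 for WT and HEA, 0.0155 and 0.0171 for WT and RA, and 0.0301 and 0.0496 for HEA and RA, at 4 h and 8 h, beside a simulated covariance of 0.0156 (SD 0.0097, highest 0.0413). Pairs taken across the 2 times share no EV libraries. Their Pearson r across genes was 0.182 (WT at 4 h, HEA at 8 h) and 0.269 (WT at 8 h, HEA at 4 h), 0.251 (HEA at 4 h, RA at 8 h) and 0.177 (HEA at 8 h, RA at 4 h), and for WT and RA the sign turned, with -0.0582 (WT at 4 h, RA at 8 h) and -0.095 (WT at 8 h, RA at 4 h).

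The change against EV at 8 h was tested against that at 4 h, and few genes passed after adjustment. At an unadjusted p under 0.05 limma had 1395 genes for WT, 408 for HEA and 256 for RA, and 1437 for EV at 8 h against 4 h. Chance alone would put a share of 0.05 of the 12268 tested genes there. The WT and EV counts lie above that share and the HEA and RA counts below it, so the latter are no sign of time changes. In WT 2 genes passed, Smad3, a mediator of TGF-beta signals, with a difference of -0.48 ± 0.077 (adjusted p = 0.0357) and Gcnt4, a glycan-building enzyme, with -0.84 ± 0.14 (0.0357). Smad3 stood at 40.9 ± 1.3 RPKM in EV and 25.9 ± 1.4 in WT at 8 h. In HEA 2 passed, Steap1, a membrane protein of the STEAP family, with -0.64 ± 0.11 (0.0372) and L3mbtl3, a chromatin reader, with -0.83 ± 0.14 (0.0372). In RA limma called 0 genes, with the 256 at an unadjusted p under 0.05 given above and 0 with voom. Between EV at 8 h and 4 h, 3 genes were lower at 8 h: Gjb2, a connexin, went from 29.8 ± 2.9 to 13.4 ± 1.8 RPKM (adjusted p = 0.00544), and Kcnk10 (-0.46 ± 0.079) and Slc4a4 (-0.59 ± 0.10), a potassium channel and a bicarbonate carrier, also passed (adjusted p = 0.048 for both). These 7 genes were chosen after their values were seen. The counts of 2, 2 and 3 are not stable: the WT count ran from 0 to 13, the HEA count from 0 to 2 and the EV count from 0 to 4 when a library was left out. With the trend on reads per base removed they were 0, 2 and 6.

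Transcripts of RNA quality and other cell types were looked at as background. Of 5 nuclear and RNA quality transcripts 1 was higher and 0 lower in WT at 8 h, and adjusted over the list alone 1 and 0 (adjusted p = 0.126, adjusted p = 0.444 with an estimated correlation). Xist, a nuclear RNA, was at 0.37 ± 0.095 (adjusted p = 0.0051), and Rmrp and Rpph1, the RNA parts of RNase MRP and RNase P, at 0.10 ± 0.059 and 0.08 ± 0.064, neither passing. Rmrp and Rpph1 lay above 1 read per base (1.5 and 1.2). In all 24 libraries Rmrp had 393 to 429 reads and Rpph1 360 to 402, so their RPKM moves against the library total and tells little of RNA quality. In HEA at 8 h 3 of the 5 were higher and 0 lower, or 5 and 0 adjusted over the list alone (adjusted p = 0.13, adjusted p = 0.929 with an estimated correlation). With fry the list passed in WT (0.0142) and HEA (0.00195) at 8 h. The list's 5 members include 3 above 1 read per base, and mean totals at 8 h were 11.7 M in EV, 10.8 in WT and 10.4 in HEA, so these list results are not read as a difference in RNA quality. Xist was at 0.27 ± 0.095 in HEA at 4 h (adjusted p = 0.0273) and 0.31 ± 0.095 at 8 h (0.0105). The 4 h call was lost without EV at 4 h replicate 1 (0.0571), EV at 4 h replicate 2 (0.0774), HEA at 4 h replicate 1 (0.0582) or HEA at 4 h replicate 2 (0.154), and without the 3 farthest libraries (0.0722), and the 8 h call without EV at 8 h replicate 1 (0.0559), EV at 8 h replicate 3 (0.0523) or HEA at 8 h replicate 1 (0.0861). In WT at 4 h Xist was at 0.18 ± 0.095, and in RA at 0.01 ± 0.095 and -0.08 ± 0.095, none of these passing. The epithelial, macrophage, endothelial, muscle and adipocyte lists had 0, 4, 1, 1 and 1 members past the filter. None of the 5 passed in any of the 6 comparisons against EV, where adjusted p ran from 0.76 to 0.999 with camera. Single markers were called in HEA: 1 adipocyte marker was higher at each time, 1 muscle marker higher and 2 lower at each time, 1 epithelial marker lower at 4 h and 1 macrophage marker higher at 8 h. In WT 1 muscle marker was lower at each time, and in RA 0 markers were called by limma. In WT at 8 h the lists' adjusted p was 0.958 (epithelial, macrophage, endothelial and muscle) or 0.979 (adipocyte). Cd68, a macrophage marker, had the highest level among them, 14.1 RPKM in WT at 8 h, and Krt19, an epithelial keratin, reached 0.827 RPKM in RA at 4 h.

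The authors' deposited table of comparisons was set beside these calls. For WT it calls 2091 of the tested genes at 4 h and 4210 at 8 h, of which 2044 and 3815 were called here with the same sign. For HEA it calls 4059 and 6444, with 3930 and 5386 in common, and for RA 629 and 1840, with 412 and 333 in common. In all 6 comparisons 0 genes were called with opposite signs in limma and in the authors' deposited table. In that table P2ry2 has log2 fold changes of 2.52 at 4 h and 3.31 at 8 h in WT, and Cdkn1a 1.94 and 2.28 in HEA.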

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

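The test of a standing difference between populations, and the fit with the axis covariate, were chosen only after the result they bear on was seen. The test of a change between 4 h and 8 h pointed to 4 genes. Smad3 differed by -0.48 and Gcnt4 by -0.84 between the WT effects at the 2 times, and Steap1 by -0.64 and L3mbtl3 by -0.83 between the HEA effects, each on the log2 scale. Smad3 was at -0.17 against EV at 4 h and -0.65 at 8 h, Gcnt4 at -0.37 and -1.21, Steap1 at -0.61 and -1.25, and L3mbtl3 at 0.63 and -0.20.

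For each comparison of 3 libraries with 3, 10 splits exist, the real one being 1 of them, too few for a share under 0.05. Each other split mixes libraries of the 2 groups. Where the groups differ, this shrinks the contrast and widens the spread. Low counts from the other splits were thus to be foreseen and add no support to the real counts. The real counts against EV were 3196, 5303 and 652 (WT, HEA, RA) at 4 h and 4324, 5853 and 341 at 8 h, with a highest other split of 1 in WT at 4 h and 0 in the other 5. Between forms at 4 h they were 6073 (WT and HEA), 4272 (WT and RA) and 5674 (HEA and RA), with a highest other of 0, 1 and 1. At 8 h they were 5887, 5122 and 5513, with a highest other of 0 in each, and EV at 8 h against 4 h had 3, with a highest other of 0. For the changes between times 100 splits were drawn. As many genes as the real 2 came from 7 splits in WT (highest other 361) and from 11 in HEA (2 genes, highest other 734), and all 100 reached the real 0 in RA (highest other 308), so chance is not excluded for these counts. Splits that call several times the real count point to a structure among the samples, and what it comes from was not tested.

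Genes with many reads had values in a narrow range, with a mean over 24 libraries of at most 1.91 reads per base among genes of 500 bases or more. The 244 genes above 1 read per base followed their library's total with a median elasticity (the slope of a gene's log reads on the log total) of 0.472, against 1.26 for 3971 genes at 0.05 to 0.2 reads per base, a difference of -0.788 (-0.834 to -0.624 when a library was left out). This is consistent with a ceiling on reads per base, such as the removal of duplicate reads would set, a step not given in the sources used here. Reads lost to near-identical copies were predicted to lower the top of the range in the 258 genes with an annotated copy. The 99th percentile of reads per base of genes without a copy was 0.672 times that of genes with one (0.6 to 0.775). Only pseudogenes named after their gene counted as copies, and the 2 sets can differ in abundance for other reasons. The ratio thus does not decide whether reads were lost to copies. If the ceiling holds, the RPKM of genes above 1 read per base, Rps18 among them, moves against the library total, so small differences of such genes between groups can come from the totals, and their true size stays open. Genes just below 1 read per base were not tested.

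Libraries of a group differed along a shared axis that held 32.0% of the variance within groups, with EV at 4 h replicate 2 (score 20.7), WT at 4 h replicate 3 (-23.4) and WT at 8 h replicate 3 (23.1) farthest out. GC content of the transcript took a share of 0.27 of the variance of the genes' loadings (11465 genes), so a GC bias between libraries is a candidate explanation for part of the axis. Gene length took 0.0384. The library total had a Pearson r of -0.169 with the score within groups over 24 libraries (permutation p = 0.472; Spearman rho = -0.190, permutation p = 0.429). Without the 2 libraries whose totals were most extreme relative to their groups the Pearson r was -0.376, so a part for the library total stays open. What else differs along the axis stays open, and no biological explanation was tested.

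HEA differed from EV in more genes than WT did, already at 4 h (5303 against 3196). With the axis score as a covariate the counts at 4 h rose in both, to 6376 in HEA and 4400 in WT. HEA still had more. The axis was taken from the residuals of the same fit, so the covariate lowers the residual spread and can raise counts for that reason alone. These counts thus do not decide whether the axis has a part in the difference. Of the lists of epithelial, macrophage, endothelial, muscle and adipocyte markers, 0 of 5 rose as a list in HEA at both times, while 1 adipocyte and 1 muscle marker were higher and 2 muscle markers lower at each time. With 0, 4, 1, 1 and 1 members past the filter this bears only on those 5 types as lists, and other cell types were not tested. A standing difference between separately infected populations predicts a slope near 1 of the 8 h on the 4 h fold changes, and the slope was 1.13 in HEA (1.04 to 1.2 when a library was left out). The WT slope was also 1.13 (0.896 to 1.5). With the noise of the fit removed, the variance across genes of the change between times did not come out above 0 in HEA, also when a library was left out. Its SD is therefore set to 0, which does not measure an absence of change. In WT the SD was 0.186 (0.0473 to 0.256), and the 2 values do not decide between these explanations. Libraries without OHT were not used here, so a standing difference and an early effect of HEA cannot be told apart. An effect of the HEA form itself stays open.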

How the results depend on the processing

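Voom, the axis covariate, GC removal, removal of the reads-per-base trend, CPM and the fit without the 3 farthest libraries were chosen after seeing the data, and the cause was not tested for any change given here. Of 508 named gene values past the threshold, quantile normalisation lost 16, median centring 14, no filter 22 and no trend 8. A pseudocount of 0.1 lost 2 and of 1 lost 2. A fit of only the groups compared lost 79, voom 8, the replicate block 11, the axis covariate 3 and reads-per-base removal 17. GC removal lost 7 of 505, omission of the 3 farthest libraries 30 of 381, and leaving out 1 library 282 of 3048 checks. In all of these 0 reversed. With only the groups compared calls were 1112 (WT 4 h), 3 (RA 4 h), 1310 (RA 8 h), 3945 (WT against HEA 4 h), 2793 (WT against RA 4 h), 1 (WT time change) and 0 (EV times). The axis covariate gave 1550 (RA 4 h), 850 (RA 8 h), 12 and 5 (WT and HEA time changes) and 30 (EV times). GC removal gave 980, 684, 23, 5 and 23 in that order. Voom gave 526 (RA 8 h), 1 (HEA time change) and 15 (EV times). Reads-per-base removal gave 0 (WT time change) and 6 (EV times). Without the 3 farthest libraries there were 335 (RA 4 h), 0 (WT time change) and 0 (EV times), and ribosomal proteins in RA at 4 h reversed (adjusted p = 0.941). Time changes in WT were 24 with quantile normalisation, 1 with median centring, 4 without the filter and 0 without the trend; in HEA 1, 0 and 6 with the first 3 of these; EV times gave 6, 5, 18 without the trend and 1 with a pseudocount of 1. Leaving out 1 library, calls ran from 2040 to 3479 (WT 4 h), 4323 to 5304 (HEA 4 h), 158 to 557 (RA 4 h), 3332 to 3980 (WT 8 h), 4715 to 5356 (HEA 8 h), 59 to 189 (RA 8 h), 4856 to 5967 (WT against HEA 4 h), 3256 to 4079 (WT against RA 4 h), 4774 to 5677 (HEA against RA 4 h), 5106 to 5609 (WT against HEA 8 h), 4286 to 4857 (WT against RA 8 h), 4507 to 5074 (HEA against RA 8 h), 0 to 13, 0 to 2 and 0 to 0 (WT, HEA and RA time changes) and 0 to 4 (EV times). Of 60 list calls against EV an estimated correlation left 0 in each of the 6 comparisons, fry lost 18 (13, 3 and 5 called in HEA 4 h, RA 4 h and RA 8 h), median centring 8 (3 left in HEA 8 h), reads-per-base removal 17 (3 left in RA 4 h and 3 in HEA 8 h), and the block 0. Replicate numbers share only a number: 30 of 84 same-numbered pairs correlated above 0.1 and 9 of 24 libraries correlated best with their own number. With the replicate block calls were 3066, 5196 and 527 (WT, HEA, RA at 4 h), 4233, 5751 and 268 (8 h), 0 for each time change and 3 for EV. CPM in place of RPKM left the Esr1 and Myc calls on the same side of the threshold and gave 5.08 to 5.45 for Esr1 in place of 3.96 to 4.09. The tests set for count files were not run, since the files used hold RPKM. Depth of 9.82 to 12.8 M reads limits genes of low RPKM.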

Other observations

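The E-box test among genes higher in WT and lower in HEA was chosen only after the result was seen. The clock genes Arntl and Nr1d1 changed in opposite directions in WT and HEA. Arntl, the Bmal1 activator, went from 8.63 ± 0.35 RPKM in EV to 2.02 ± 0.60 in WT and 13.7 ± 0.40 in HEA at 8 h (-1.89 ± 0.13 and 0.64 ± 0.13), and Nr1d1, its repressor Rev-erb alpha, from 9.03 ± 1.8 to 32.0 ± 2.3 and 5.21 ± 0.41 (1.79 ± 0.13 and -0.72 ± 0.13). The direct difference of WT and HEA at 8 h was -2.53 ± 0.13 for Arntl (adjusted p = 6.1e-12) and 2.51 ± 0.13 for Nr1d1 (6.45e-12). Bhlhe41, also a clock gene, rose in WT by 1.78 ± 0.22 and was at -0.04 ± 0.22 in HEA (adjusted p = 0.887). In RA the values of Arntl and Nr1d1 at 8 h were -0.05 ± 0.13 and 0.06 ± 0.13, neither passing. Of 17 clock genes 4 were higher and 4 lower in WT at 8 h, or 4 and 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.855, adjusted p = 0.857 with an estimated correlation), with a median of -0.01, a mean of 0.09 and an upward direction in camera. In HEA at 8 h 5 were higher and 7 lower, or 6 and 8 adjusted over the list alone, and the list did not pass either (adjusted p = 0.804, adjusted p = 0.929 with an estimated correlation).

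Partners and antagonists of Myc moved in different directions. In WT at 8 h Mxd4, a repressor that binds Max, fell from 24.04 ± 2.2 to 11.3 ± 1.6 RPKM (-1.06 ± 0.15), and it rose in HEA to 36.9 ± 5.7 (0.60 ± 0.15). Mxi1, another such repressor, rose in both WT (0.78 ± 0.12) and HEA (0.91 ± 0.12), and Max rose in WT (0.46 ± 0.089), as did Mlxip (0.88 ± 0.15) and Mga (0.36 ± 0.071). Mxd3 fell in WT and HEA (-0.71 ± 0.16 and -0.74 ± 0.16) and Mlx in HEA (-0.67 ± 0.14). Mxd1 (-0.54 ± 0.17 in WT) passed but not without EV at 8 h replicate 1 (0.0654), EV at 8 h replicate 3 (0.0509), WT at 8 h replicate 1 (0.0832) or WT at 8 h replicate 2 (0.0679). Mycl, a relative of Myc, went from 1.24 ± 0.046 to 6.73 ± 1.2 RPKM in HEA (2.04 ± 0.16) and to 0.635 ± 0.063 in WT (-0.61 ± 0.16, adjusted p = 0.00526). Of 11 members 4 were higher and 5 lower in WT at 8 h, or 5 and 5 adjusted over the list alone, and the list did not pass (adjusted p = 0.751, adjusted p = 0.778 with an estimated correlation), its median (-0.14) and mean (-0.07) being below 0 and camera's direction upward.

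A hypothesis was that genes with the E-box CACGTG, a site bound by Myc with Max, in the first 300 bases of their transcript respond to MycER. The transcripts of 11465 tested genes (93.5%) were searched, and 621 (5.42%) carried it. Genes higher in WT at 8 h carried it in 9.84% of cases against 4.62% of the other genes, an odds ratio of 2.25 (95% interval 1.87 to 2.71, Fisher's exact test adjusted over 6 sets p = 1.45e-15), beside 0.605 to 1.32 for 7 other palindromes. Genes lower in HEA at 8 h carried it in 7.89% against 4.43%, an odds ratio of 1.85 (1.56 to 2.19). Fisher's exact test adjusted over 6 sets gave p = 2.96e-12, and the other palindromes had odds ratios of 0.872 to 1.19. Among these genes lower in HEA, the share was 21.8% in those higher in WT, 6.43% in those not called in WT and 4.93% in those lower in WT. The raised share thus lay mainly in genes that were also higher in WT, a split that was not tested for this set. The odds ratio was 0.631 (0.497 to 0.794) for genes lower in WT, beside 0.728 to 1.28 for the other palindromes, and 0.533 (0.411 to 0.682) for genes higher in HEA, beside 0.761 to 1.16. For genes higher in RA it was 0.400 (0.107 to 1.05, Fisher's exact test adjusted p = 0.077), resting on 4 of 177 genes, and another palindrome reached 2.38 in that set. For genes lower in RA it was 0.998 (0.421 to 2.03), resting on 8 of 148. The interval of the former argues against a raised share, a depletion is not shown for it, and the latter holds too few genes to decide.

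Of 417 searched genes higher in WT and lower in HEA at 8 h, 91 (21.8%) carried the E-box, against 82 of 1342 (6.11%) other genes higher in WT, an odds ratio of 4.28 (3.07 to 6.0, Fisher's exact test p = 3.28e-18). Part of the E-box genes may thus be ones on which WT and HEA act in opposite directions, a hypothesis found and tested on the same data. Besides those 91 genes, the E-box was carried by 10 of 358 genes lower in WT and higher in HEA at 8 h (2.79%). Of genes higher in both forms 31 of 599 (5.18%) carried it, and of genes lower in both 54 of 1096 (4.93%). For genes called in HEA alone it was 35 of 1369 higher (2.56%) and 113 of 1758 lower (6.43%). For genes called in WT alone it was 51 of 743 higher (6.86%) and 27 of 956 lower (2.82%). Of genes called in neither 209 of 4169 (5.01%) carried it, beside 5.42% of all searched genes. The searched part starts at the annotated transcript and leaves out the promoter upstream of it.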
